A study of Mus musculus with 9 samples.

How the data were processed

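RNA sequencing counts were taken from 9 mouse libraries, 3 from primary prostate tumours, 3 from proximal metastases in the epididymal fat and 3 from distal metastases. Per the labels, all animals were C57BL/6 mice of about 9 to 10 months with prostate-specific deletion of exon 3 of 1 Ctnnb1 allele, which stabilises beta-catenin, among their engineered changes. Groups follow the tissue labels, and the library numbers 1 to 3 within a group only name the libraries. For the distal group the tissue label names the diaphragm and the growth protocol names the lung, so "distal" is used throughout. The labels state that the samples were matched within 3 mice, but do not state which samples came from the same mouse. No animal term could therefore be fitted, and the p-values treat the 9 libraries as independent.

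Each deposited file held raw, whole-number counts per Ensembl gene for 1 library, with 47069 gene rows. Per the submitters' processing notes, the tools named were FastQC 0.11.4, TopHat2 2.1.0, Bowtie2 2.2.6.0, HTSeq 0.6.0, R 3.2.3 and DESeq2 1.14.1, with the genome build GRCm38.p3. The strand setting of the counting, the annotation release and the read filters are not given in the sources used here. Counts of overlapping or antisense genes, and of near-identical gene copies, are therefore uncertain. Of the 47069 identifiers, 46488 were matched to a gene symbol, and the other 581 kept their identifier. Gene positions, lengths and GC content were taken from GENCODE release M21 on GRCm38. No library was identical to another or within sampling noise of it: the lowest chi-square per gene between any 2 libraries was 25.5, where sampling noise alone gives about 1.

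Total counts ranged from 28334730 in primary 3 to 40408723 in distal 2. Before scaling, a gene at 1 CPM (a count scaled to the library total) holds 28.3 to 40.4 counts in a library, depending on its depth. Shares of counts in a single library carry a 95% Wilson interval, which also covers counting error only. Where a group summed to 3 or fewer counts for a gene, the ratio was given with its exact Poisson interval, which covers counting error only. CPM values were computed here from the deposited counts, with library totals scaled by the trimmed mean of M values (TMM).

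Genes with enough counts (edgeR's filterByExpr by group, minimum count 10, minimum total 15) were tested: 18204 passed and 28865 did not. The test was edgeR 4.0.16's quasi-likelihood F-test with robust shrinkage in R 4.3.3, fitted on all 9 libraries with 6 residual degrees of freedom. The 4 comparisons were proximal against primary, distal against primary, distal against proximal, and the mean of both metastatic sites against primary. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Standard errors (SE) are the absolute log2 fold change divided by the square root of F. The fit took 1 dispersion per gene for all groups. The median SD of log2 CPM, however, was 0.614 in primary, 0.174 in proximal and 0.163 in distal libraries. SEs and p-values of the comparisons against primary can therefore be too small. Those of distal against proximal can be too large for the same reason. The groups, tests, 31 gene lists, alternatives and the rule for naming genes were fixed before the data were examined. The rule took, per comparison and direction, the 8 called genes with the largest change that reached 10 CPM in the higher group and whose groups did not overlap, without predicted or clone-based names or antigen receptor segments. It also took up to 4 called members of each list described, filled up to 2 members by mean expression, and a fixed panel that included Ctnnb1, Axin2, Nkd1, Krt5, Krt8, Cdh1, Vim and Mki67. Any other gene named is said to have been chosen after its values were seen.

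Lists were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the 31 lists of a comparison. Alternatives were camera with an estimated correlation and fry. No list call held with an estimated correlation or with fry in any of the 4 comparisons, so the adjusted p with an estimated correlation stands beside each list described. Alternatives for the gene counts were median-ratio size factors, library totals alone, DESeq2 1.42.0, limma-voom, 2 other filters, no robust shrinkage, a fit of the compared groups alone, a minimum log2 fold change of 1, removal of the 10 most abundant and the 37 mitochondrially encoded genes, and leaving out each library in turn. Added after seeing the data were voom with sample quality weights, offsets for GC content and transcript length (available for 99.6% of the tested genes), and removal of CT010467.1 and Lars2.

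The comparison of the proximal and distal contrasts used 20 simulations of unchanged groups sharing the 3 primary libraries, with 1 dispersion per gene for all groups. Added after seeing the data were 20 simulations with a dispersion per gene and group, and the variance within the primary libraries of log2 CPM (prior count 0.125) divided by 3. The functions were tested on simulated counts with 200 genes changed and 1 dispersion per gene for all groups, so the greater spread of the primary libraries is not in these shares. For proximal against primary, with 17935 simulated genes tested, 54% of the genes changed by a log2 fold of 2 and 90% of those changed by 4 were recovered. The shares were 55% and 91% for distal against primary (17909 genes), 52% and 88% for distal against proximal (17946 genes), and 54% and 93% for both sites against primary (17976 genes). Between 3.31% and 7.55% of the calls in these simulations were unchanged genes. Figures were drawn with matplotlib 3.10.9.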

Results

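Bulk RNA was sequenced from primary prostate tumours and their metastases in mice whose prostate epithelium carries stabilised beta-catenin. The 9 libraries comprised 3 primary tumours, 3 proximal metastases from the epididymal fat and 3 distal metastases, labelled as diaphragm in one field and lung in another. Total counts were 35565887, 32232486 and 28334730 in primary 1, 2 and 3. They were 38563934, 37786289 and 40084408 in proximal 1, 2 and 3, and 39319712, 40408723 and 29094545 in distal 1, 2 and 3. The labels state that the samples were matched within 3 mice without saying which belong together, so all comparisons are unpaired.

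The gene whose product is stabilised in the mouse model was measured in every library. Ctnnb1, which encodes beta-catenin (ENSMUSG00000006932, chromosome 9, 120929216 to 120960507 on GRCm38, overlapping Ulk4 on the other strand), stood at 4399, 937 and 1771 CPM in primary 1, 2 and 3. It averaged 4328 ± 670 CPM (SD, n = 3) in the proximal and 4074 ± 467 CPM (SD, n = 3) in the distal metastases. It did not pass the test in any comparison against primary (lowest edgeR adjusted p = 0.267). All samples carry the same genotype, so its counts check no label.

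The metastases resembled each other closely, whereas the primary tumours differed. Across genes, the correlation of log2(CPM + 1) lay between 0.985 and 0.993 among the proximal libraries, between 0.979 and 0.990 among the distal libraries and between 0.976 and 0.993 across the metastatic sites. Among the primary libraries it lay between 0.872 and 0.930. Primary 1 had a mean correlation of 0.975 with the 6 metastases and 0.898 with the other primary tumours. The corresponding values were 0.868 and 0.901 for primary 2, and 0.907 and 0.927 for primary 3. Genes are not independent replicates, so these correlations carry no p-value. The median SD of log2 CPM per gene was 0.614 in primary, 0.174 in proximal and 0.163 in distal libraries.

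**Figure D1:**
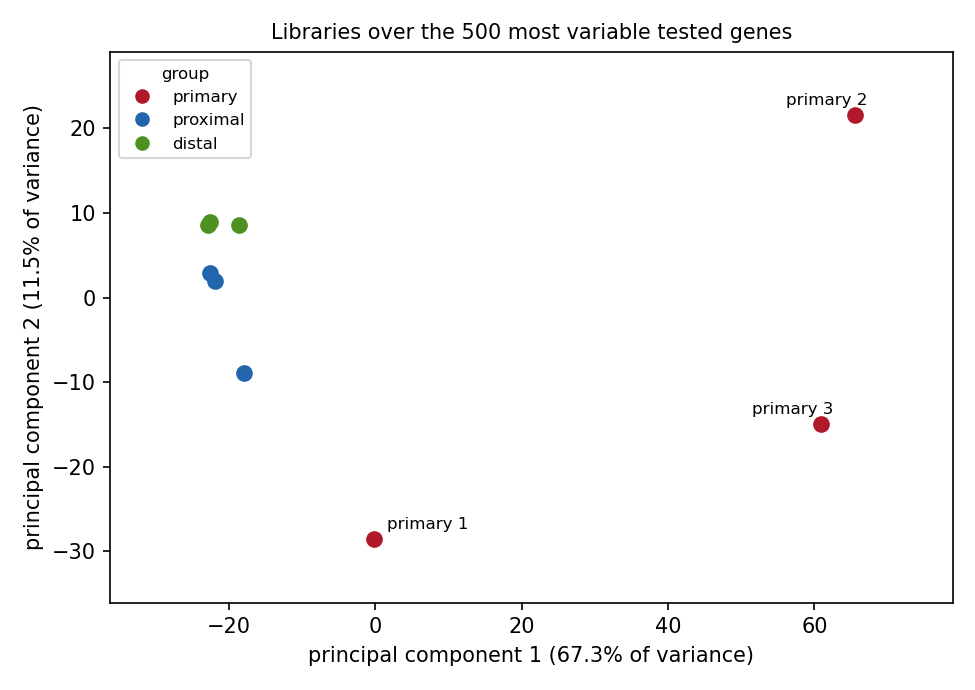
Principal components 1 and 2 of the 9 libraries, computed over the 500 most variable tested genes, with axes in component scores and points coloured by group. Component 1 holds 67.3% of the variance; primary 2 and primary 3 lie at 65.6 and 60.9 on it, primary 1 at -0.105 and the 6 metastases between -22.9 and -18.0.

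Libraries also differed in composition. Primary 2 had 2.28% of its counts on CT010467.1 (95% Wilson interval 2.27% to 2.28%) and 1.87% on Lars2 (1.87% to 1.88%), against at most 0.236% and 0.238% in the other libraries. Mitochondrially encoded genes held 0.131% of its counts (0.130% to 0.132%), against 0.868% to 1.18% in the others. Its TMM factor was 0.795, against 0.994 to 1.05 in the others. Primary 3 held transcripts of the seminal vesicle, an accessory sex gland: the seminal vesicle list summed to 7502 CPM there, 29.9 CPM in primary 2, 9.9 CPM in primary 1 and 2.2 to 12.8 CPM in the metastases. Svs2, a major seminal vesicle secretory protein gene, alone reached 5254 CPM in primary 3. The epididymis list summed to 112.6 CPM in primary 3, against 0.586 to 2.67 CPM in the other 8 libraries.

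Proximal metastases were compared with primary tumours to find the genes whose expression differs between the tumour in the prostate and its nearby spread. The called genes were lower in the metastases. Ceacam1, a cell adhesion molecule of epithelial surfaces (ENSMUSG00000074272, chromosome 7, 25461707 to 25477603), fell from 66.1 ± 20.7 to 3.09 ± 0.623 CPM (SD, n = 3 each; log2 fold change -4.42, SE 0.36, edgeR adjusted p = 0.0278). Klf4, a transcription factor of epithelial differentiation (ENSMUSG00000003032, chromosome 4, 55527143 to 55532466), fell from 67.8 ± 18.7 to 14.98 ± 0.585 CPM (log2 fold change -2.18, SE 0.22, adjusted p = 0.0295). Tspan1, a tetraspanin, fell from 333 ± 230 to 8.53 ± 3.35 CPM (log2 fold change -5.29, SE 0.61, adjusted p = 0.0455). Adgrg7, an adhesion G protein-coupled receptor gene, fell from 151 ± 97.2 to 0.823 ± 0.519 CPM (log2 fold change -7.52, SE 0.86, adjusted p = 0.0454).

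Cds1, an enzyme of phospholipid synthesis, changed by -4.31 (SE 0.45), the glycosyltransferase gene B3gnt7 by -6.42 (SE 0.65) and Fxyd4, a regulator of the sodium pump, by -7.72 (SE 0.77) on the log2 scale, each with an edgeR adjusted p of 0.0295. Atp12a, a proton-potassium pump of epithelial surfaces (ENSMUSG00000022229, chromosome 14, 56365068 to 56388550, overlapping Gm10873 on the other strand), held 3 counts over the proximal libraries and 2031 over the primary ones. Its primary level was 868 times the proximal level, with a counting interval of 297 to 4208, and its adjusted p was 0.0295. The remaining called gene was Mgat4a, named here after its values were seen. In all, 9 of 18204 genes were called, each lower in the proximal metastases, with every primary library above every proximal one. Such separation holds for 10% of genes by chance in 3 against 3 and held for 19.4% of all tested genes, and a small p favours it. At an unadjusted p below 0.05 there were 3313 genes, 702 higher and 2611 lower.

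These counts depended on single libraries and on the tool. Without primary 1, 5447 genes were called, 2622 of them higher. Without primary 2 there were 22, without primary 3 there were 2, without distal 3 there was 1, and without distal 1, distal 2 or any of the proximal libraries there was none. None of the 8 genes named by the rule stayed called in all 9 fits that leave out a library, with a highest adjusted p of 0.274 for 7 of them and 0.406 for Tspan1. Leaving out a library moved the fold by over 1.5 times for Atp12a (log2 fold change -8.59 without primary 1), Fxyd4 (-6.80 without primary 3) and Tspan1 (-4.63 without primary 2). DESeq2 called 1528 genes, 123 higher and 1405 lower, limma-voom called 1, and a fit of the 6 compared libraries alone called none.

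Among the lists, epithelial programmes stood lower in the proximal metastases against primary tumours. The squamous differentiation list was shifted lower, with 20 of 20 tested members at negative log2 fold changes (camera adjusted p = 4.45e-09; adjusted p = 0.649 with an estimated correlation). No member was called over all genes, and 16 were called lower when adjusted over the list alone. Its most abundant members were Dsp, a desmosome gene, at -0.16 (SE 0.17), and Krt4, a keratin, at -0.97 (SE 0.61). The luminal and secretory prostate list (camera adjusted p = 2.21e-07), the basal epithelium list (7.46e-06) and the epithelial junction and identity list (1.73e-07) were also shifted lower, each at an adjusted p = 0.649 with an estimated correlation. None of their members was called over all genes, and 12 of 21, 13 of 18 and 12 of 20 were lower when adjusted over the list alone, with 1 basal member higher, the laminin gene Lamb3 at 0.67 (SE 0.20). The keratin gene Krt8 stood at a log2 fold change of -1.44 (SE 0.48, edgeR adjusted p = 0.203) and Cdh1, the E-cadherin gene, at -2.14 (SE 0.64, adjusted p = 0.181), neither past the threshold.

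Lists of other cell types and responses were shifted lower as well in the proximal metastases: interferon response (camera adjusted p = 2.21e-07), macrophage (1.72e-05), neutrophil (0.000510), immediate early and stress (0.00926), endothelium (0.0183), seminal vesicle (0.0252), lung epithelium (0.0259) and urothelium (0.0358). Each stood at an adjusted p = 0.649 with an estimated correlation. The interferon sum was 396 CPM in primary 1, within the proximal range of 373 to 441 CPM, and 920 and 1233 CPM in primary 2 and 3. The urothelium sum was 461 CPM in primary 1, against 463 to 537 CPM in the proximal libraries and 841 and 930 CPM in primary 2 and 3. The macrophage sum of primary 1 (567 CPM) lay above the proximal ones (268 to 525 CPM). When adjusted over the list alone, 15 of 24 interferon, 5 of 17 macrophage, 1 of 14 neutrophil, none of 16 immediate early, none of 16 endothelial, 4 of 4 seminal vesicle, 3 of 9 lung epithelium and 4 of 9 urothelium members were lower. Urothelium lost its call without primary 1, primary 3 or proximal 1 (up to 0.297, without primary 3), lung epithelium without primary 3 (0.0824) and endothelium without primary 1 (0.200). The complement gene C1qa, a macrophage marker, stood at a log2 fold change of -1.65 (SE 0.44) and Lyz2, a lysozyme gene, at -0.89 (SE 0.44), neither called. The cell division list was shifted higher, with 25 of 28 members positive (camera adjusted p = 1.72e-05; adjusted p = 0.649 with an estimated correlation) and none called over all genes or over the list alone. Its sum was 1489 CPM in primary 1, within the proximal range of 1158 to 1769 CPM, and 988 and 882 CPM in primary 2 and 3. Mki67, a marker of dividing cells, stood at 216 ± 62.6 CPM in proximal and 130 ± 62.0 CPM in primary samples (SD, n = 3 each; log2 fold change 0.73, SE 0.36, edgeR adjusted p = 0.303).

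**Figure D2:**
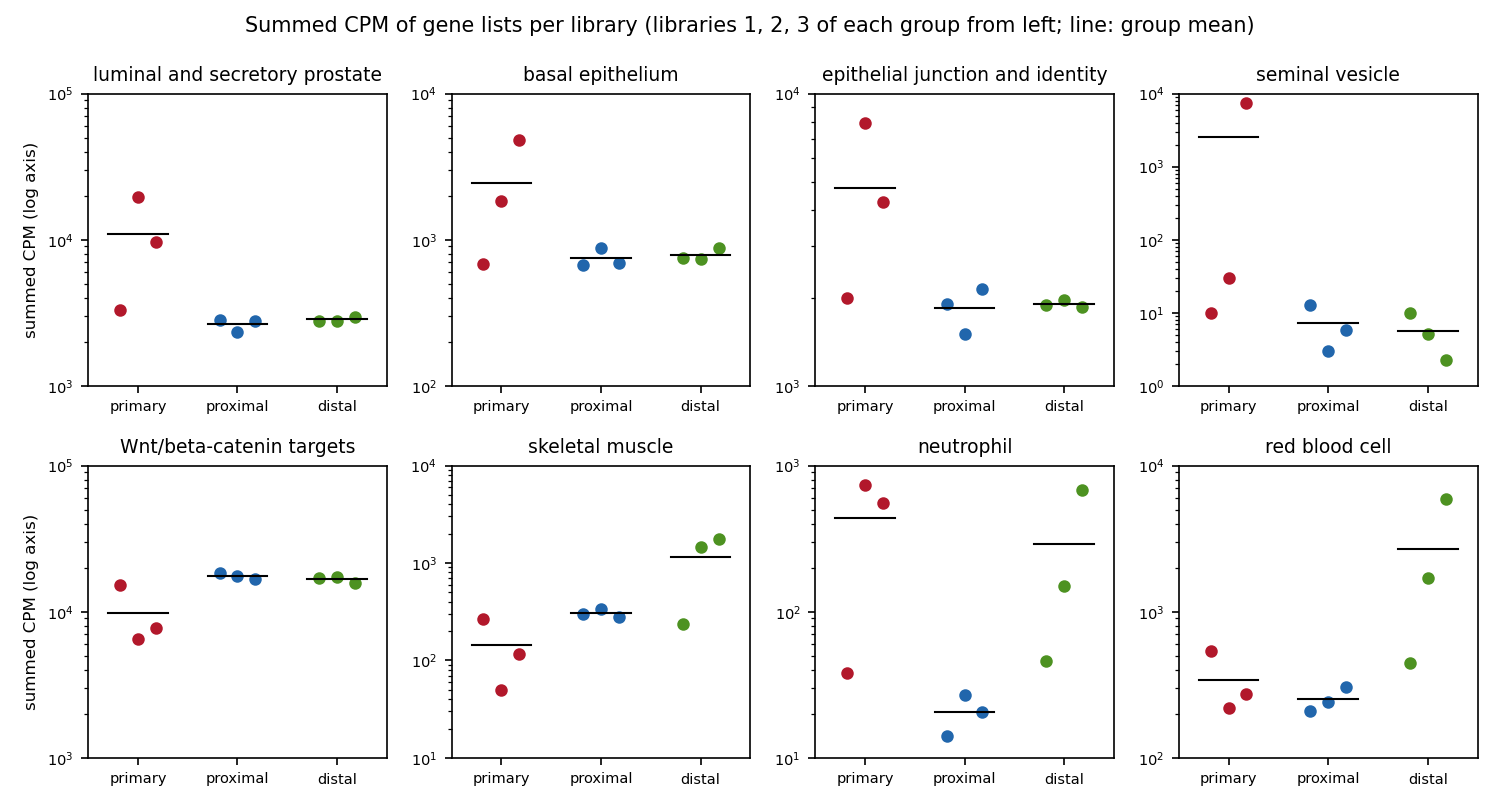
Summed CPM of 8 gene lists in each library, on log axes that span whole decades, with libraries 1, 2 and 3 of a group from left to right and a line at the group mean. Primary 1 lies close to the metastases for the epithelial lists and the Wnt list (15171 CPM, against 6541 and 7711 CPM in primary 2 and 3), and distal 2 and distal 3 have the highest skeletal muscle sums.

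Distal metastases were compared with primary tumours in the same way. Again the called genes were lower in the metastases. Cldn7, a tight junction claudin (ENSMUSG00000018569, chromosome 11, 69964779 to 69967885), fell from 150 ± 110 to 3.15 ± 0.388 CPM (SD, n = 3 each; log2 fold change -5.58, SE 0.68, edgeR adjusted p = 0.0466). Wfdc2, which encodes a secreted protein of glandular epithelium, fell from 68.4 ± 43.5 to 0.236 ± 0.121 CPM (log2 fold change -8.12, SE 0.97, adjusted p = 0.0441). The amino acid transporter gene Slc6a14 changed by -8.99 (SE 1.13, adjusted p = 0.0476) and Pof1b, a gene of epithelial junctions, by -6.60 (SE 0.78, adjusted p = 0.0441). Upk1a, a uroplakin of the bladder lining, changed by -4.55 (SE 0.51, adjusted p = 0.0391). Adgrg7, B3gnt7, Fxyd4 and Atp12a changed by -8.42 (SE 0.90), -6.33 (SE 0.65), -6.52 (SE 0.72) and -8.97 (SE 0.94), with adjusted p values of 0.0378, 0.0378, 0.0391 and 0.0378.

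In all, 16 genes were called in the distal metastases, each lower and each separating the groups, where chance separates 10% of genes and 18.8% of all tested genes separated. At an unadjusted p below 0.05 there were 3165 genes, 708 higher and 2457 lower. Without primary 1, edgeR called 5203 genes (2516 higher), without primary 2 it called 26, without distal 1 it called 35 (32 higher), and without primary 3, distal 2, distal 3 or any of the proximal libraries none. None of the 9 named genes stayed called in all 9 such fits, with highest adjusted p values between 0.313 and 0.427. The fold of 6 of them moved by over 1.5 times without a single library: Fxyd4 (-5.59) and Pof1b (-5.96) without primary 3, Cldn7 (-4.86) and Wfdc2 (-7.51) without primary 2, Atp12a (-8.12) without primary 1 and Slc6a14 (-9.61) without distal 1. DESeq2 called 1508 genes, 219 higher and 1289 lower, limma-voom called 1, and a fit of the 6 compared libraries alone called none.

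Among the lists, 7 were shifted higher and 11 lower in the distal metastases against primary tumours. For the squamous, junction, luminal and basal lists, the sums in primary 1 again lay near those of the metastases. Lower were squamous differentiation (camera adjusted p = 6.50e-09; 14 of 20 members lower when adjusted over the list alone), epithelial junction and identity (9.48e-08; 12 of 20), luminal and secretory prostate (4.83e-07; 11 of 21), basal epithelium (1.09e-05; 11 of 18, with 1 higher), urothelium (0.00588; 5 of 9) and lung epithelium (0.00833; 1 of 9), each at an adjusted p = 0.549 with an estimated correlation. Seminal vesicle was lower too (0.0106; 4 of 4; adjusted p = 0.551 with an estimated correlation). Over all genes, only Cldn7 and Upk1a were called among the members of the lists named in this paragraph. Interferon response (0.00126), T cell (0.00142), macrophage (0.00231) and B and plasma cell (0.0219) were lower as well, at an adjusted p of 0.678, 0.664, 0.655 and 0.720 with an estimated correlation and with no member called over the list alone. Without primary 3, the calls of interferon response (0.151), urothelium (0.0966) and B and plasma cell (0.173) were lost, the last also without primary 1 (0.301) and distal 1 (0.0969). The interferon sum was 396 CPM in primary 1, below the distal range of 408 to 624 CPM, and 920 and 1233 CPM in primary 2 and 3.

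The lists shifted higher in the distal metastases against primary tumours included markers of other tissues. The skeletal muscle list had 17 of 18 members positive (camera adjusted p = 6.50e-09; 13 of 18 higher when adjusted over the list alone), the red blood cell list 8 of 8 (0.000252; 5 of 8) and the hepatocyte list 14 of 17 (0.000334; 5 of 17, with 1 lower), each at an adjusted p = 0.549 with an estimated correlation. Acta1, skeletal muscle actin, stood at 239 ± 211 CPM in the distal and 1.23 ± 1.11 CPM in the primary libraries (SD, n = 3 each; edgeR adjusted p = 0.120). Cell division (9.98e-09; 28 of 28 positive), mesenchymal transition (0.0163; 13 of 18), neutrophil (0.0219; 13 of 14) and Wnt/beta-catenin targets (0.0473; 18 of 26) were also shifted higher, without any member called. Their adjusted p values with an estimated correlation were 0.549, 0.678, 0.720 and 0.662. The neutrophil sum went against its shift, at 292 ± 341 CPM in distal and 440 ± 360 CPM in primary libraries (SD, n = 3 each). Its member Ltf held 607 and 482 CPM in primary 2 and 3, and at most 14.2 CPM in a distal library. The cell division sum was 1489 CPM in primary 1, within the distal range of 1440 to 1852 CPM, and 988 and 882 CPM in primary 2 and 3. The mesenchymal call was lost without primary 2 (0.247), the neutrophil call without primary 1 (0.804), primary 3 (0.0595) or distal 3 (0.523), and the Wnt call without primary 2, primary 3, proximal 2, proximal 3, distal 1 or distal 2 (0.0526 to 0.0954). For the Wnt list the median log2 fold change was 0.44 and the mean -0.16, so the signs differed. Wif1, a secreted Wnt inhibitor induced by the pathway, stood at a log2 fold change of 1.13 (SE 0.56, adjusted p = 0.320). Apcdd1, another inhibitor of Wnt signalling, stood at 1.28 (SE 0.58, adjusted p = 0.298).

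The contrasts of both sites against primary shared their controls. All 9 genes called in the proximal metastases were also called, and also lower, in the distal ones, where independent lists of these sizes would share 0.00791 genes. Unchanged groups with shared controls, simulated 20 times with each group's own dispersion, shared 1.30 genes on average (range 0 to 6), and none with 1 dispersion per gene for all groups. Across the 18204 genes, log2 fold changes correlated at r = 0.828, against a mean of 0.767 (range 0.751 to 0.784) with each group's own dispersion and 0.506 with 1 for all. Both contrasts had the same sign for 89.9% of genes, against 82.8% and 66.7%, and the covariance was 1.30, against 0.324 and 0.177. The simulations with each group's own dispersion spread more than the libraries: their median SD of log2 CPM was 0.713, 0.240 and 0.270 in primary, proximal and distal libraries, against 0.604, 0.172 and 0.161 computed in the same way from the counts. Taken from the counts, the variance within the primary libraries divided by 3 was 0.444, out of a covariance of 1.31 between fold changes of mean log2 CPM. That variance rests on 3 libraries, so the remainder is not read as a change shared by the sites. The 3 controls cannot be split into sets of at least 2 libraries, so part of the excess over independent lists may come from sharing them. Without primary 1 the overlap was 4729 genes, without primary 2 it was 22, without any other single library none, and with DESeq2 1092.

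Distal and proximal metastases were compared to ask whether the sites differ. The lists with the smallest p values were markers of other tissues and blood. The skeletal muscle list summed to 237, 1451 and 1763 CPM in distal 1, 2 and 3, against 282 to 340 CPM in the proximal libraries, and was shifted higher (camera adjusted p = 1.02e-44; adjusted p = 0.0594 with an estimated correlation; 15 of 18 members higher when adjusted over the list alone). Acta1 stood at 3.43, 307 and 408 CPM in distal 1, 2 and 3 and at most 0.862 CPM in the proximal libraries. The neutrophil list was shifted higher, with 14 of 14 members positive (5.69e-42; adjusted p = 0.0594 with an estimated correlation; 12 of 14 over the list alone), among them S100a9, a neutrophil granule protein gene, at 12.0, 50.8 and 247 CPM in distal 1, 2 and 3. The red blood cell list was shifted higher in 8 of 8 members (1.52e-26; adjusted p = 0.0594 with an estimated correlation; 8 of 8 over the list alone), with the globin gene Hbb-bs at 278, 1209 and 4081 CPM in distal 1, 2 and 3. The hepatocyte list was shifted higher (3.73e-19; adjusted p = 0.0722 with an estimated correlation; 7 of 17 over the list alone), while its sum, most of it Alb, averaged 6562 ± 633 CPM in distal and 6902 ± 1352 CPM in proximal libraries (SD, n = 3 each).

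Further lists passed the test between the sites. Interferon response (camera adjusted p = 1.71e-10; median log2 fold change 0.91), smooth muscle (8.97e-10; 0.99), immediate early and stress (6.37e-06; 0.38), macrophage (0.000776; 0.26), cell division (0.00129; 0.16), neuroendocrine (0.0366; 0.38) and mesenchymal transition (0.0375; 0.11) were shifted higher in the distal metastases. Their adjusted p values with an estimated correlation were 0.470 for interferon response, 0.376 for smooth muscle and for immediate early and stress, and 0.762 for the others. Adipocyte (2.95e-05; -0.27), T cell (0.00166; -1.28), B and plasma cell (0.0294; -1.50) and urothelium (0.0460; -0.18) were shifted lower, each at an adjusted p = 0.762 with an estimated correlation. No member of these 11 lists was called over the list alone.

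Of the 15 lists called between the sites, 6 kept their call whichever library was left out: skeletal muscle, neutrophil, red blood cell, hepatocyte, interferon response and smooth muscle. Without proximal 2, T cell (0.00113) and B and plasma cell (4.24e-08) were shifted higher instead of lower, and adipocyte (0.0591) and urothelium (0.309) lost their calls. The B and plasma cell list summed to 136 CPM in proximal 2, against 6.9 and 5.3 CPM in proximal 1 and 3 and 4.9, 21.7 and 27.2 CPM in distal 1, 2 and 3. Without distal 3, neuroendocrine was shifted lower instead of higher (0.00354), and immediate early and stress (0.253), macrophage (0.710) and mesenchymal transition (0.0766) lost their calls. Without proximal 3, cell division (0.713), macrophage (0.351), mesenchymal transition (0.368), neuroendocrine (0.116) and urothelium (0.100) lost theirs. Without distal 1, adipocyte, T cell, B and plasma cell, urothelium and mesenchymal transition did (0.432 to 0.547), and without distal 2 cell division (0.186), adipocyte (0.117) and urothelium (0.101). Without proximal 1, mesenchymal transition and neuroendocrine were lost (0.223 each). Without a primary library, urothelium and B and plasma cell lost their calls in each case (0.0511 to 0.0840), neuroendocrine without primary 1 (0.160) or primary 2 (0.0588), and mesenchymal transition without primary 3 (0.0904). The neuroendocrine member Chgb, a chromogranin gene, stood at 134 CPM in distal 3 and at most 0.970 CPM in the other metastases.

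Gene by gene, no difference between distal and proximal metastases was called with edgeR, and limma-voom also called none. The dispersion shared with the more variable primary libraries can make this test too strict. An edgeR fit of the proximal and distal libraries alone, however, called none either. At an unadjusted p below 0.05 edgeR gave 375 genes, 326 of them higher in the distal metastases, and DESeq2 called 133, 121 of them higher. Without distal 1, edgeR called 38 genes, all higher. The smallest edgeR adjusted p was 0.999985.

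Both metastatic sites combined, 6 libraries against the 3 primary ones, gave the most calls. Hoxb13, a homeobox gene of prostate epithelium (ENSMUSG00000049604, chromosome 11, 96194316 to 96197447), fell from 112 ± 96.1 CPM in primary tumours to 4.15 ± 0.779 in proximal and 3.998 ± 0.900 CPM in distal metastases (SD, n = 3 each; log2 fold change -4.77, SE 0.47, edgeR adjusted p = 0.00732). The claudin genes Cldn3 (ENSMUSG00000070473, chromosome 5, 134986214 to 134987472, overlapping Wbscr25 on the other strand) and Cldn7 changed by -6.47 (SE 0.62, adjusted p = 0.00672) and -5.30 (SE 0.50, adjusted p = 0.00669) on the log2 scale. Krt5, a basal cell keratin, stood at 15.4, 144 and 1356 CPM in primary 1, 2 and 3 and at most 2.79 CPM in a metastasis (log2 fold change -8.57, SE 1.24, adjusted p = 0.0190). H19, an imprinted non-coding RNA (ENSMUSG00000000031, chromosome 7, 142575529 to 142578143, overlapping Mir675), rose from 10.5 ± 4.43 to 55.8 ± 16.5 CPM in proximal and 52.4 ± 7.46 CPM in distal metastases (log2 fold change 2.36, SE 0.33, adjusted p = 0.0170).

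Psat1, an enzyme of serine synthesis, was also higher in both sites together (log2 fold change 0.91, SE 0.19, edgeR adjusted p = 0.0455). Psat1 kept its call in only 1 of the 9 fits that leave out a library, with an edgeR adjusted p of up to 0.186. Lower were Fam25c (-9.79, SE 1.63), at 0.376, 172 and 10.1 CPM in primary 1, 2 and 3, Atp12a (-9.20, SE 0.70), Sp8, a transcription factor gene (-9.14, SE 1.34), Pigr, the receptor that carries antibodies across epithelia (-9.04, SE 1.25), and Slc6a14 (-9.01, SE 0.83), with adjusted p values between 0.00373 and 0.0257. Without primary 2 the log2 fold changes of Fam25c, Pigr and Sp8 were -6.27, -6.71 and -7.98, without primary 1 that of Atp12a was -8.35, and without proximal 1 that of Slc6a14 was -9.76. The gasdermin genes Gsdmc2 (-9.16, SE 1.13) and Gsdmc3 (-8.99, adjusted p = 0.00986) were called too. Gsdmc4 (adjusted p = 0.0260) held 3 counts over the 6 metastases, a ratio of 1249 with a counting interval of 427 to 6057. Without primary 3, Gsdmc2 and Gsdmc3 stood at -6.82 and -7.38, and without primary 1 Gsdmc4, whose fitted value was -10.44, stood at -8.45. These near-identical neighbours on chromosome 15 can share reads, so their separate values are uncertain.

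In all, 676 genes were called between both sites and the primary tumours, 6 higher and 670 lower, and 513 of them separated the groups, where chance separates 2.38% of genes in 6 against 3 and 10.2% of all tested genes separated. At an unadjusted p below 0.05 there were 4483 genes, 1099 higher and 3384 lower. Without primary 1, 6618 genes were called, 3081 higher and 3537 lower, among them all 676. Without primary 2, primary 3 and proximal 2 there were 251, 88 and 134, and without proximal 1, proximal 3, distal 1, distal 2 and distal 3 there were 27, 28, 23, 22 and 43. DESeq2 called 2546 genes (400 higher, 2146 lower) and limma-voom 97. Of the 44 named genes called in this comparison, 6 stayed called whichever library was left out: Atp12a, Slc6a14, Hoxb13, Cldn3, Cldn7 and Upk1a. H19 kept its call without primary 1, primary 2, proximal 1 or proximal 2, and its adjusted p without another library ranged up to 0.0804, reached without primary 3. Krt5 kept its call without each primary library and lost it without each metastasis, up to an adjusted p of 0.108 without distal 2. The fold moved by over 1.5 times without a single library for 31 of the 44, for Krt5 to -5.90 without primary 3, and for Hoxb13 and Cldn7 to -3.79 and -4.58 without primary 2.

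**Figure D3:**
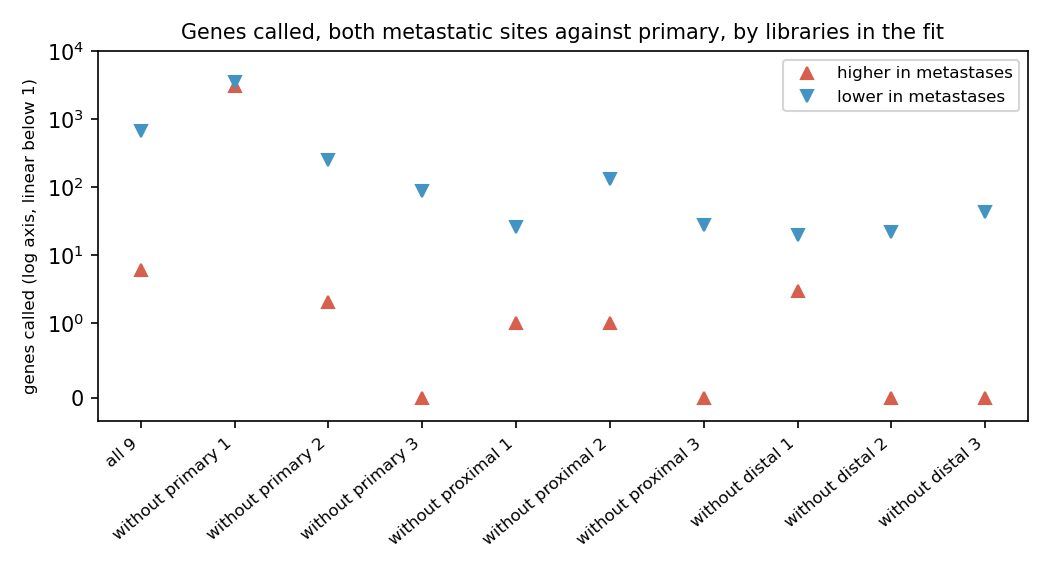
Genes called higher (upward triangles) and lower (downward triangles) in both metastatic sites against primary tumours, with all 9 libraries and without each library in turn, on an axis that is logarithmic above 1. The counts were 6 higher and 670 lower with all libraries, and 3081 higher and 3537 lower without primary 1.

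By list, both sites together were shifted lower in 4 epithelial lists. The list sums of primary 1 lay near those of the metastases, and those of primary 2 and primary 3 were higher. For squamous differentiation primary 1 summed to 927 CPM (metastases 769 to 920) and for basal epithelium to 681 CPM (669 to 884). For the luminal list it summed to 3290 CPM (2320 to 2949) and for the junction list to 1994 CPM (1505 to 2149). Single members such as Hoxb13 and Tgm3 lay higher in primary 1 than in any metastasis. Of the squamous differentiation list, 10 of 20 members fell, including the transglutaminase gene Tgm3 (-8.58, SE 0.87), Ivl, a protein of the cornified envelope (-7.20, SE 0.99), and the keratin genes Krt6a (-8.19, SE 1.20) and Krt16 (-8.13, SE 1.36), and 18 fell when adjusted over the list alone (camera adjusted p = 1.85e-09). Of the basal epithelium list, 9 of 18 fell, including Perp (-3.54, SE 0.51), Sfn (-4.57, SE 0.69) and Col17a1, a hemidesmosome collagen (-7.45, adjusted p = 0.0209), with 14 lower and 1 higher over the list alone (5.37e-06). Of the luminal and secretory prostate list, 7 of 21 fell, including Hoxb13, Ppp1r1b (-7.46, SE 0.83), Tgm4, a secreted transglutaminase of the prostate (-7.40, SE 0.96), and Pigr, and 14 over the list alone (2.03e-07). Of the epithelial junction and identity list, 4 of 20 fell, which were Cldn3, Cldn7, the protease gene Prss8 (-5.72, SE 0.73) and the splicing regulator gene Esrp1 (-3.86, SE 0.51), and 12 over the list alone (1.74e-07). The adjusted p with an estimated correlation was 0.692 for each of these lists. Without primary 3, Krt16, Krt6a, Col17a1, Tgm4, Perp and Ivl stood at -5.51, -6.03, -5.22, -5.76, -2.53 and -6.40, and without primary 2, Ppp1r1b and Sfn at -6.01 and -3.89.

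Further lists shifted lower in both sites together were interferon response (5 of 24 called lower, 12 over the list alone; camera adjusted p = 9.26e-06), with Ifih1, a sensor of viral RNA, at -3.35 (SE 0.56), and macrophage (none of 17, 4 over the list alone; 0.000181). Urothelium (3 of 9, 5 over the list alone; 0.0128), seminal vesicle (3 of 4, 4 over the list alone; 0.0128), lung epithelium (1 of 9, 3 over the list alone; 0.0133), T cell (none of 17 under either adjustment; 0.00940) and endothelium (none of 16, 3 over the list alone; 0.0353) were shifted lower too. The adjusted p with an estimated correlation was 0.746 for T cell and endothelium and 0.692 for the others. Without primary 3, the calls of urothelium (0.121), lung epithelium (0.0565) and T cell (0.111) were lost and Ifih1 stood at -2.59, and that of endothelium was lost without primary 1 (0.277), proximal 1 (0.0552), proximal 3 (0.0548) or distal 1 (0.0879). The seminal vesicle sum was high in primary 3 alone. The interferon sum was 396 CPM in primary 1, within the 373 to 624 CPM of the metastases, and 920 and 1233 CPM in primary 2 and 3. The urothelium sum was 461 CPM in primary 1, within the 422 to 557 CPM of the metastases. The called lung epithelium member was Slc34a2, a phosphate transporter gene (-7.98, SE 0.81), at 3.33, 59.3 and 44.7 CPM in primary 1, 2 and 3.

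Cell division (27 of 28 members positive; camera adjusted p = 5.09e-07) and skeletal muscle (16 of 18 positive; 0.00109) were shifted higher in both sites together, with no member called under either adjustment and an adjusted p of 0.692 and 0.746 with an estimated correlation. The cell division sum was 1489 CPM in primary 1, within the 1158 to 1852 CPM of the metastases, and 988 and 882 CPM in primary 2 and 3. The skeletal muscle sum was 1451 and 1763 CPM in distal 2 and 3, but 237 CPM in distal 1, 282 to 340 CPM in the proximal libraries and 266 CPM in primary 1. Of the proximal sums, 203 to 249 CPM was the member Mybpc1, at 176 CPM in primary 1, while Acta1 reached at most 0.862 CPM there. The shift is therefore not read as muscle in both sites. Wnt/beta-catenin targets were not called (0.0683; adjusted p = 0.746 with an estimated correlation), with a median log2 fold change of 0.46 and a mean of -0.18. Over the list alone 1 member was higher and 5 lower. Sfrp5 and Dkk2, both secreted Wnt antagonists, fell (-3.52, SE 0.66, and -3.64, SE 0.70) over all genes, though of the 9 fits that leave out a library both were called only in that without primary 1, and without primary 2 they stood at -2.96 and -2.63, while Axin2 and Nkd1, feedback inhibitors induced by the pathway, stood at 0.61 (SE 0.23, edgeR adjusted p = 0.168) and 0.35 (SE 0.26, adjusted p = 0.367). Vim, a mesenchymal intermediate filament gene, stood at 2065, 227 and 371 CPM in primary 1, 2 and 3, and Cdh1 at 292, 2423 and 885 CPM. Neither was called (adjusted p = 0.337 and 0.0613).

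**Figure D4:**
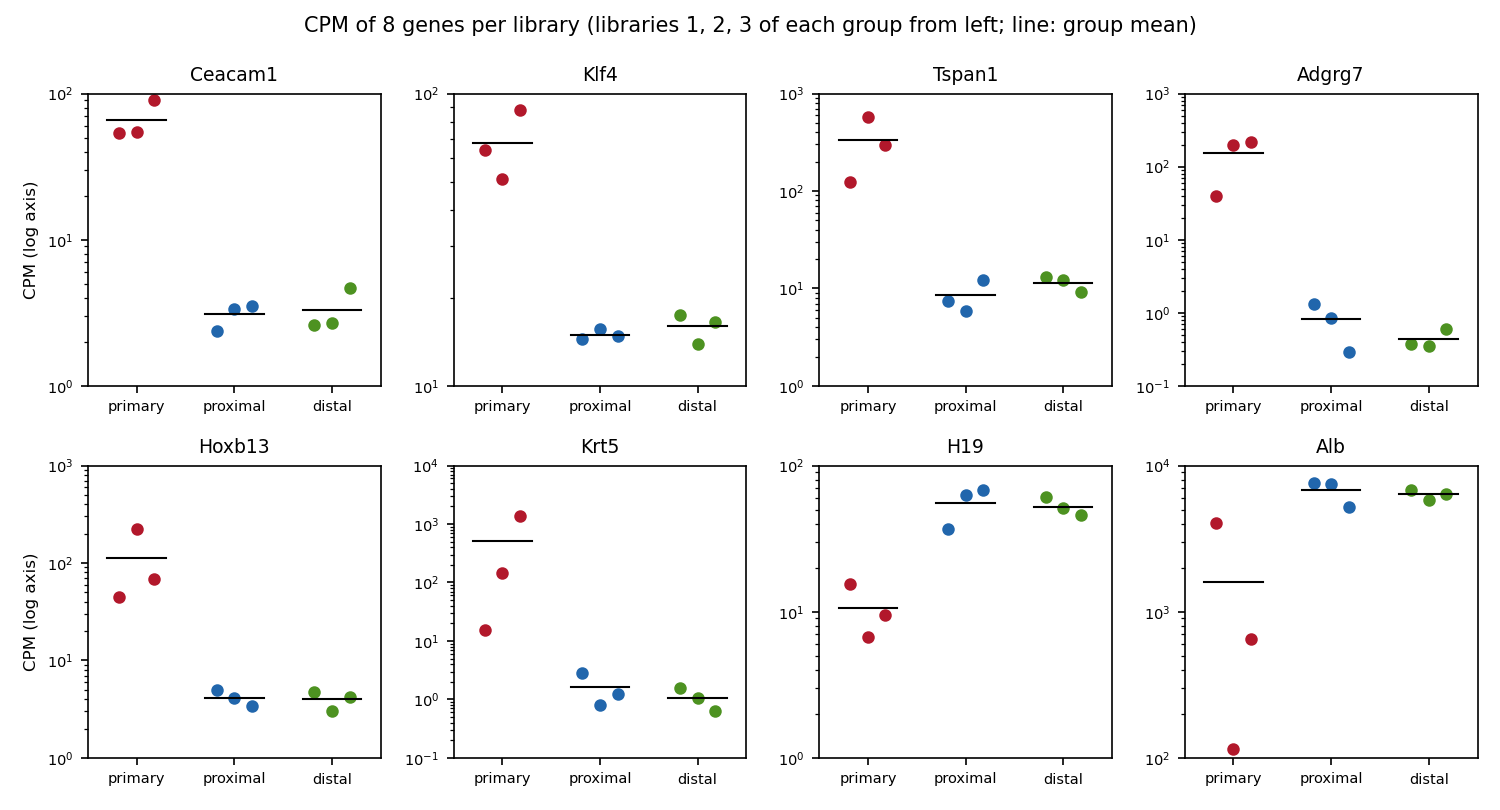
CPM of 8 genes in each library, on log axes that span whole decades, with libraries 1, 2 and 3 of a group from left to right and a line at the group mean. Ceacam1, Klf4, Tspan1, Adgrg7, Hoxb13 and Krt5 lie higher in every primary library than in any metastasis, while H19 and Alb lie lower in every primary library than in any metastasis.

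The remaining lists were called in none of the 4 comparisons: hair follicle keratins and regulators (lowest camera adjusted p = 0.263), matrix remodelling and invasion (0.164), hypoxia and glycolysis (0.147), FOXO-responsive genes (0.441), epididymis (0.290), mesothelium (0.290), fibroblast (0.400) and mitochondrial respiration (0.0795). Single members were called in both sites together, among them Mmp7, a secreted matrix protease (-8.49, SE 1.40, edgeR adjusted p = 0.0255), which stood at 40.8, 16869 and 2023 CPM in primary 1, 2 and 3 and at most 29.9 CPM in a metastasis, and Adamts1 (-3.01, SE 0.51, adjusted p = 0.0258). Without primary 2 they stood at -5.89 (adjusted p = 0.0523) and -2.39 (adjusted p = 0.0769), and each kept its call in 1 of the 9 fits that leave out a library. For the conflicting label of the distal site, the lung epithelium list summed to 10.3, 12.6 and 18.8 CPM in distal 1, 2 and 3 and to 8.0, 28.6 and 11.6 CPM in proximal 1, 2 and 3. The skeletal muscle list summed to 237, 1451 and 1763 CPM in distal 1, 2 and 3 and to 299, 340 and 282 CPM in proximal 1, 2 and 3. Muscle markers thus stood out in distal 2 and distal 3, and lung markers in no distal library. For distal 1 these sums favour neither label.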

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

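In this part, the tests of where primary 1 lies, of the share of lower calls without primary 1 and with GC and length offsets, and of seminal vesicle tissue were chosen after the result was seen.

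The effects of the metastatic sites against primary differed, by the test of distal against proximal, for 15 lists (camera adjusted p). Higher in distal were skeletal muscle (1.02e-44), neutrophil (5.69e-42), red blood cell (1.52e-26), hepatocyte (3.73e-19), interferon response (1.71e-10), smooth muscle (8.97e-10), immediate early and stress (6.37e-06), macrophage (0.000776), cell division (0.00129), neuroendocrine (0.0366) and mesenchymal transition (0.0375). Lower were adipocyte (2.95e-05), T cell (0.00166), B and plasma cell (0.0294) and urothelium (0.0460). None held with an estimated correlation, where the lowest adjusted p was 0.0594. Without proximal 2, T cell (0.00113) and B and plasma cell (4.24e-08) were shifted higher instead, and adipocyte (0.0591) and urothelium (0.309) were not called. Without distal 3, neuroendocrine was shifted lower (0.00354).

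Other groupings of the same libraries were fitted to see how often they call as many genes. For proximal against primary the real grouping gave 9 genes and the highest other gave 0, for distal against primary 16 and 0, and for distal against proximal 0 and 0. At least as many genes came from 1, 1 and 10 of the 10 splits, the real one included, and 10 splits are too few for a share below 0.05. For both sites against primary, refitted as 2 groups, the real split gave 1101 genes and the highest other 1181. Of 84 splits, the real one included, 2 gave at least as many, a share below 0.05. That share would exclude chance only if the libraries could be exchanged freely. The primary libraries spread more than the others (median SD of log2 CPM 0.614, against 0.174 in proximal and 0.163 in distal libraries), so the share does not decide the question. The samples are matched within 3 mice in a way the labels do not give, so the splits ignore that matching. The split with the higher count set primary 2, primary 3 and distal 3 against the rest, so the count does not single out the real grouping.

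Primary 1 lay with the metastases and apart from primary 2 and primary 3, and leaving it out raised the calls in both sites against primary from 676 to 6618. A swap with a primary tumour that resembles primary 2 and primary 3 needs a partner among the metastases that lies with them. The tables argue against such a swap. The mean correlation with primary 2 and primary 3 minus that with the other metastases was at most -0.0874 over the 6 metastasis libraries. A swap with a primary tumour that itself resembles the metastases would not show in this test, so it stays open. The split that exchanges primary 1 with distal 3 called 1181 genes, against 1101 for the real one. A metastasis library free of primary tissue under the label of primary 1 is also argued against: over 89 genes called lower without primary 1 in a fit of the metastases as 1 group, below 0.5 CPM in metastases and at least 10 CPM in the other primary libraries, primary 1 lay above all of 5 metastases, averaged over the sets of 5, in 78.3%, and a left-out metastasis in 5.68% to 36.5%. A metastasis sample mixed with some primary tissue stays open. Over the 7261 genes called in that fit (6618 with the sites as separate groups), the median position of primary 1 was 0.0457 (0 at the metastases, 1 at the other primary libraries). That lay within the range of -0.0608 to 0.0941 of left-out metastases. A primary tumour with fewer non-malignant cells may give the same values, which was not tested. Marker sums of such cells went both ways. Of the primary libraries, primary 1 had the highest fibroblast (3489 CPM), smooth muscle (646 CPM) and adipocyte (964 CPM) sums. It had the lowest macrophage (567 CPM) and neutrophil (38.0 CPM) sums. Of the neutrophil sums of 733 and 550 CPM in primary 2 and 3, the member Ltf held 607 and 482 CPM. The luminal sum was also lowest in primary 1 (3290 CPM, against 19609 and 9717 CPM in primary 2 and 3). So were the basal (681 CPM, against 1826 and 4841 CPM) and seminal vesicle sums (9.9 CPM, against 29.9 and 7502 CPM). The luminal and basal lists cannot tell malignant from non-malignant epithelium.

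The calls in both sites against primary lay almost entirely on the lower side, 670 of 676, and the tables argue against GC content and gene length, because with offsets for both the share of lower calls stayed at 98.3%. The fitted trend with GC content and length was strongest in primary 2 (SD 0.400 on the log2 scale, against at most 0.111 in another library). Primary 2 was the highest library for 45.4% of the 670 genes. Seminal vesicle tissue as the source of all lower calls is argued against as well: its transcripts summed to 7502 CPM in primary 3 and at most 29.9 CPM in primary 1 and primary 2, yet only 47.2% of the 670 genes (counting interval 43.4% to 50.9%) were highest in primary 3. For the 316 genes highest there it stays open: 13.6% of them were still called lower without primary 3, against 100% without primary 1, 34.2% without primary 2 and 2.85% to 19.3% without a metastasis. The position of primary 1 near the metastases for genes higher in metastases may account for the few higher calls, since without primary 1 the share of higher calls was 46.6%. Loss of epithelial programmes in the metastases, and other non-malignant epithelium in the primary samples, were not tested and stay open.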

How the results depend on the processing

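Fits with voom sample quality weights, GC and length offsets and without CT010467.1 and Lars2 were chosen after seeing the data. No paired analysis was possible because the labels do not say which samples came from the same mouse, so the p-values ignore that matching. No called result of a named gene changed sign under the alternatives run.

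For genes called in proximal against primary (9), distal against primary (16), distal against proximal (0) and both sites against primary (676), DESeq2 gave 1528 (123 higher, 1405 lower), 1508 (219, 1289), 133 (121, 12) and 2546 (400, 2146). Quality weights gave 3607 (1479, 2128), 3126 (1187, 1939), 0 and 3871 (1535, 2336), and limma-voom 1, 1, 0 and 97. Median-ratio size factors moved the first count to 15, GC and length offsets to 16, no robust shrinkage to 22 and no low-count filter to 26. Library totals alone moved the second to 10. A minimum of 10 CPM in 3 samples moved the second to 10 and the last to 57, with fewer genes tested. Fitting the compared groups alone, with fewer samples, gave 0 and 0 for the first pair and 0 for distal against proximal. For both sites together it is the same fit. The cause of the other changes was not tested. A minimum fold and removal of abundant genes or of CT010467.1 and Lars2 left all 4 counts within 1.5 times.

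Leaving out a library gave ranges of 0 to 5447, 0 to 5203, 0 to 38 and 22 to 6618 genes, with the highest count without primary 1 except for distal against proximal, where it was without distal 1. The overlap of proximal and distal calls (9) ranged from 0 to 4729, and was 1092 with DESeq2. Of the named genes called, 0 of 8, 0 of 9 and 6 of 44 stayed called in all 9 such fits, for proximal, distal and both sites against primary.

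The lists called numbered 13, 18, 15 and 13 in the 4 comparisons, and 0 in each with an estimated correlation or with fry. Without a library they ranged from 12 to 18, 14 to 22, 12 to 16 and 12 to 18. Depth limits the ratios given for Atp12a and Gsdmc4, at 3 counts over a group.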

Other observations

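The tests of hepatocyte genes beside Alb were chosen after the result was seen, and that of its paralogs before. Alb, the serum albumin gene of hepatocytes (chromosome 5, 90460897 to 90476602), was singled out after its values were seen. It stood at 4035, 114 and 650 CPM in primary 1, 2 and 3, 6758 ± 1321 CPM in proximal and 6358 ± 501 CPM in distal metastases (SD, n = 3 each), and was not called in both sites against primary (log2 fold change 2.03, SE 0.93, edgeR adjusted p = 0.217). Hepatocytes in the samples are argued against as the source, because the highest of 7 other abundant hepatocyte genes, Ahsg, reached 0.111% of Alb in the median over the 6 metastases, and at most 0.808% in any of them. Reads shared with a paralog are argued against too, since Afp, the highest of 3 paralogs by median, stood at 0.0183% of Alb in the median over the 6 metastases, and none exceeded 0.416%, reached by Gc, in any of them. Expression of Alb by the tumour cells may account for the values, a hypothesis for which no biological test was made.

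The following genes were chosen after their values were seen. Star and Cyp11a1, which act in steroid hormone synthesis, reached 892 and 418 CPM in distal 3 and at most 4.68 and 0.261 CPM in the other metastases, and Chga, a chromogranin gene, reached 135 CPM in distal 3 and at most 0.715 CPM in the others. Fgb, a fibrinogen gene of hepatocytes, stood at 27.7, 5.15 and 1.17 CPM in distal 1, 2 and 3 and at most 0.122 CPM in the proximal libraries. Adipoq, an adipocyte hormone gene, stood at 5.67, 27.6 and 10.9 CPM in proximal 1, 2 and 3, and at 0.0750, 0.0953 and 18.2 CPM in distal 1, 2 and 3. Pbsn, the prostate secretory protein gene probasin, stood at 0.483, 211 and 11.8 CPM in primary 1, 2 and 3 and at most 0.888 CPM in a metastasis.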
